A study of Homo sapiens with 8 samples.

How the data were processed

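Total RNA, depleted of ribosomal RNA and made into libraries with a KAPA HyperPrep kit, was sequenced from the Nthy-ORI thyroid epithelial cell line. The 8 libraries fell into 4 groups of 2 by the treatment and time in their labels: vehicle or 10 nM T3, each for 6 h or 24 h. The deposited values were raw read counts per gene symbol, 1 column per library, neither normalised nor pooled. Per the submitters' processing notes, the tools were CASAVA 1.7, STAR 2.7, HTSeq and DESeq2, and the genome build was hg38. The annotation release, the strand setting of the counting and any trimming of reads are not given in the sources used here. Antisense and overlapping genes can therefore share reads in ways that cannot be traced, and near-identical copies such as HSPA1A and HSPA1B, the metallothioneins and the histones are uncertain individually.

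Each library held 56832 gene rows and 5 summary rows, which were left out of the library sizes and tests. Reads counted in genes made up 12.9% to 24.4% of the reads in a library's table. Reads that did not align uniquely made up 47.6% to 67.4%, and reads outside annotated features took 48.2% to 58.2% of the unique ones. A library with a larger share outside features has fewer counts to measure a given gene with. The total over gene rows ran from 2517983 to 8201606 reads, so the floor of 3 counts corresponded to between 0.366 and 1.19 CPM, where CPM is the count of a gene per 1e6 counts of its library. Counting intervals are exact 95% binomial intervals. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules.

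Genes were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalisation, the filterByExpr filter by group, and the robust quasi-likelihood F test with 1 coefficient per group over all 8 libraries, which left 4 residual degrees of freedom. The filter kept 14611 genes. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and an adjusted p for a gene is from this test unless another is named. The biological coefficient of variation was 13.1%. The comparisons were T3 against vehicle at 6 h and at 24 h, vehicle at 24 h against vehicle at 6 h, and the difference between the T3 responses at the 2 times. Values per gene are TMM-scaled CPM, given as mean ± SD of the 2 libraries of a group, and log2 fold changes carry the standard error (SE) of the fit. Against a group with no counts, a fold is given as at least the ratio to 3 counts over that group. Against a group with 1 to 3 counts, the ratio of CPM is given with its counting interval.

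The groups, tests, comparisons, gene lists, most alternative settings and the rule for naming genes were set before the data were examined. The rule named, in each comparison of groups and among genes past the threshold with a mean of at least 1 CPM and no overlap between the replicates of the groups, the 10 largest rises, the 10 largest falls and the 5 smallest p-values. It added up to 4 members of each list, the 5 largest differences of response in each direction, and as fixed genes KLF9, HR, THRA, THRB, DIO1, DIO2, SMARCA4 and 8 thyroid genes. A gene outside that rule is said to have been chosen afterwards. A few genes that the rule names are not reported here.

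The 23 fixed lists held 538 entries, all found among the gene rows, 39 of them through an older symbol. They covered classical targets of thyroid hormone receptors, thyroid differentiation, receptors with their partners and transporters, SWI/SNF subunits, cell cycle, PI3K-AKT regulators, interferon and JAK-STAT genes, NF-kB and cytokines, and immediate early genes. They also covered glycolysis and hypoxia, cholesterol synthesis, fatty acid metabolism, mitochondrially encoded genes, the integrated stress and unfolded protein response, p53 targets, extracellular matrix with TGF-beta response, the epithelial-mesenchymal state, Wnt and Notch targets, and replication-dependent histones. The remaining lists held markers of fibroblasts, endothelial cells, immune cells and thyroid C cells. The 19 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, and adjusted over the lists. Members were called by the gene test, over all genes and adjusted over the list alone. A further 3 lists, namely heat shock chaperones, metallothioneins with zinc export, and cytosolic ribosomal proteins, were added after the largest changes had been seen. Their camera p-values were adjusted over these 3 lists alone.

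Gene positions, types, GC content and exon length came from the GENCODE 29 annotation of the GRCh38 genome, matched by symbol for 29526 rows and 12577 tested genes. It may not be the annotation the counts were made with. The trend of each library with GC content and length was removed in an alternative fit with lowess curves of span 0.3, entered as offsets. The alternatives fixed in advance were RLE size factors, DESeq2 1.42.0, no filter, a filter of at least 1 CPM in at least 2 libraries (meant as a stricter one, though it kept 17013 genes), replicate blocks, a fit to the 4 libraries compared, an estimated correlation in camera and leaving out each library in turn. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Alternatives chosen after seeing the data were annotated genes only, the GC and length correction with and without the block, thinning of every library to 2517983 counts, leaving out mitochondrial genes, and, for T3 at 6 h, leaving out the 627 genes over 8-fold higher at 24 h.

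The gene test was tested on simulated counts with 200 of 14611 genes changed. In the simulated 6 h comparison it recovered 8.11% of genes changed 1.5-fold, 49.2% of those changed 2-fold and 75.4% of those changed 4-fold, with 7 false calls among 91. In the simulated 24 h comparison it recovered 16.7%, 54.1% and 88.1%, with 5 false calls among 109. Of 100 random sets, camera gave 2 an unadjusted p under 0.05. Simulated genes were drawn independently, with no GC trend between T3 and vehicle and with the same spread per gene in every group. These results therefore cannot check the preset correlation, or the false calls that such trends or a spread unequal between groups would give. The 2 libraries of every group differed by more than counting noise, with a chi-square per degree of freedom of 4.11 for vehicle and 2.69 for T3 at 6 h, and 27.8 for vehicle and 7.24 for T3 at 24 h. Repeat libraries of 1 RNA sample would also exceed counting noise, so this does not show separate cultures.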

Results

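Gene expression was measured in Nthy-ORI cells, an epithelial line from normal human thyroid. The cells were kept without hormone for 24 h and then given 10 nM T3, the active thyroid hormone, or the NaOH vehicle, for 6 h or 24 h. The series concerns transcription controlled by the thyroid hormone receptor TR-beta and its need for SWI/SNF chromatin remodelers, and these libraries address which transcripts change with T3 at each time. Each of the 4 groups held 2 libraries. Reads counted in genes came to 3428165 and 2517983 for vehicle at 6 h, 3043258 and 5450752 for T3 at 6 h, 3957592 and 6743039 for vehicle at 24 h, and 6057464 and 8201606 for T3 at 24 h. Nothing states that replicates came from separate cultures, so p-values measure the spread between these libraries only, which may be technical.

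KLF9, which encodes a transcription factor, and HR, which encodes a transcriptional corepressor, are established targets of thyroid hormone receptors. KLF9 (chromosome 9, 70384597 to 70414624, minus strand, GRCh38) stood at 0.861 ± 0.0607 CPM (SD, n = 2) with vehicle and 13.7 ± 0.488 CPM with T3 at 6 h, a log2 fold change of 3.95 (SE 0.50, edgeR adjusted p = 0.0002). Its vehicle level rested on 3 and 2 counts, no more than the floor of 3 counts, so the small SD does not show precision. HR (chromosome 8, 22114415 to 22133384, minus strand) stood at 63.5 ± 7.01 and 108.8 ± 9.92 CPM, a log2 fold change of 0.77 (SE 0.17, edgeR adjusted p = 0.012). At 24 h both went the other way. KLF9 stood at 26.1 ± 7.50 CPM in the libraries labelled vehicle and 3.07 ± 0.399 CPM in the libraries labelled T3, a log2 fold change of -3.08 (SE 0.31, edgeR adjusted p = 6.75e-05). HR stood at 4.09 ± 0.288 and 0.213 ± 0.137 CPM, where the latter rested on 3 counts, a ratio of 20.4 with a counting interval of 6.54 to 102. KLF9 kept its call at both times and HR at 24 h whichever library was left out, while HR at 6 h lost it without any 1 of the 4 libraries of that time (highest edgeR adjusted p = 0.188). Because KLF9 and HR went against the labels at 24 h, every direction drawn from the 24 h libraries refers to the libraries as labelled, T3 over vehicle.

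**Figure D1:**
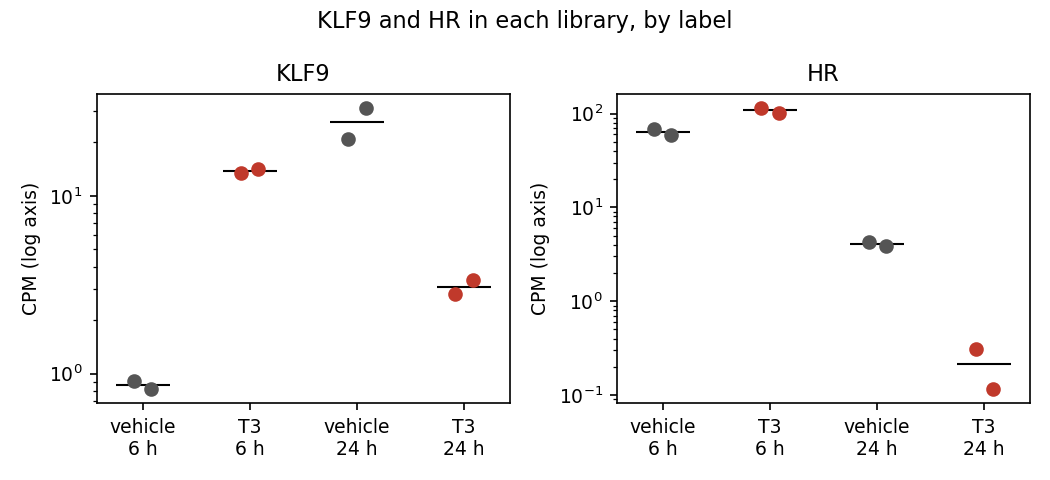
CPM of KLF9 and HR on log axes in each of the 8 libraries (points), grouped by label, with the group mean as a bar. KLF9 rises from 0.861 to 13.7 CPM with T3 at 6 h and stands at 26.1 CPM in the libraries labelled vehicle against 3.07 CPM in those labelled T3 at 24 h, and HR goes the same ways.

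At 6 h of T3, the largest rises the naming rule picked were those of the metallothionein genes MT1X and MT1F, KLF9, TNS4, TMEM158 and the heat shock gene HSPA1A. Members of the integrated stress response list (13 of 28) and of the extracellular matrix list (7 of 22) fell. Those lists had camera adjusted p = 1.03e-05 and 0.00805, and both had adjusted p = 0.175 with an estimated correlation. MT1X, a metallothionein that binds zinc and copper, went from 2.34 ± 0.747 to 117 ± 19.3 CPM (SD, n = 2 per group), a log2 fold change of 5.68 (SE 0.36, edgeR adjusted p = 2.08e-07). The zinc exporter gene SLC30A1 rose from 73.9 ± 4.31 to 252 ± 9.02 CPM, and HSPH1, which encodes a chaperone, from 298 ± 27.9 to 987 ± 51.2 CPM, both with an edgeR adjusted p = 6.37e-07. TRIB3, a pseudokinase gene induced by ATF4 and CHOP, fell from 282 ± 39.6 to 101 ± 4.29 CPM (edgeR adjusted p = 3.68e-05). FN1, which encodes fibronectin, fell from 551 ± 134 to 127 ± 8.01 CPM (edgeR adjusted p = 7.04e-07). Most of that fall could also come from reads of the 24 h kind in the vehicle libraries (log2 change -1.79, against -2.11 observed). The assumed share of such reads came from genes chosen as low in T3 replicate 1, FN1 among them, which favours this reading.

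Of 14611 genes tested, 1117 passed the threshold at 6 h, 553 higher and 564 lower, 382 of them changed at least 2-fold (edgeR with Benjamini-Hochberg adjustment). Calls of at least 2-fold numbered 98 without vehicle replicate 1, 262 without vehicle replicate 2, 109 without T3 replicate 1 and 106 without T3 replicate 2 of 6 h, 711 with only the 4 libraries compared and 197 with GC and length correction. Among the genes the naming rule picked, the other large rises were MT1F (log2 fold change 5.16, SE 0.55), TNS4, which encodes a focal adhesion protein (2.96, SE 0.26), TMEM158 (2.89, SE 0.67), HSPA1A (2.57, SE 0.19), MT2A (2.33, SE 0.24), HSPA1B (2.02, SE 0.16) and APOB (1.81, SE 0.49). APOB lost its call with GC and length correction and without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h (highest edgeR adjusted p = 0.4), with log2 fold changes of 1.07 to 3.06 over the leave-outs. TMEM158 lost its call without any 1 of the 6 h libraries (highest edgeR adjusted p = 0.204). HSPA1A and HSPA1B are near-identical and metallothioneins closely alike, so their separate values are uncertain. DPY19L2P2, a pseudogene, fell from 7.05 ± 1.02 to 0.483 ± 0.171 CPM, and HIST1H1D, a linker histone gene, by 2.55 on the log2 scale (SE 0.30). Of the 71 named genes past the threshold, 23 kept their call in every leave-out, every planned setting and the fit corrected for GC content and length.

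The list of the integrated stress and unfolded protein response fell at 6 h as a group. Of its 28 tested members 13 fell and 1 rose over all genes, and 16 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.03e-05, adjusted p = 0.175 with an estimated correlation). SESN2, a stress-induced regulator of mTORC1, fell by 1.66 on the log2 scale (SE 0.20), DDIT3, which encodes CHOP, by 1.22 (SE 0.18) and STC2, a secreted glycoprotein gene, by 1.14 (SE 0.14). Leaving out vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h left 6 members lower, and the list passed camera in every leave-out. None of the 13 was at least 8-fold higher in the 24 h libraries than with T3 at 6 h. With GC and length correction 16 members fell and 0 rose (camera adjusted p = 3.01e-07 at the preset correlation). GDF15 fell by 1.64 (SE 0.21) within the p53 target list, of whose 23 members 3 fell and 1 rose (adjusted over the list alone, 3 and 3; camera adjusted p = 0.776). DDIT4, an mTORC1 inhibitor gene, fell by 1.36 (SE 0.15) and PIK3CD by 2.10 (SE 0.27) within the PI3K-AKT list, of whose 28 members 3 fell and 1 rose (4 and 3 adjusted over the list alone; camera adjusted p = 0.86). The rising PI3K-AKT gene lost its call without any 1 of the 6 h libraries or either T3 library of 24 h, and 3 rose without either 24 h vehicle library. The rising p53 target lost its call without vehicle replicate 1 of 6 h, and 2 rose without vehicle replicate 2 of 6 h and 3 without any 1 of the 24 h libraries.

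Extracellular matrix and cytokine genes also fell at 6 h. Of 22 tested members of the matrix and TGF-beta list, 7 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.00805, adjusted p = 0.175 with an estimated correlation). Besides FN1, TGFBI fell by 0.98 (SE 0.11) and COL1A1, the type I collagen gene, by 0.90 (SE 0.13) on the log2 scale. Of 18 members of the NF-kB and cytokine list, 5 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.175 with an estimated correlation), among them CXCL8, the interleukin-8 gene, by 1.53 (SE 0.23). Of the falling members, 3 of 7 matrix genes and 3 of 5 cytokine genes were at least 8-fold higher in the 24 h libraries than with T3 at 6 h. A mixture of the T3 profile of 6 h with 3.99% of the 24 h profile was taken to stand for vehicle. That share was the mean vehicle median less the mean T3 median of 6 h, as percent of the 24 h level, over 20 genes. They were chosen for lying under 2% of that level in T3 replicate 1, which favours the pattern. FN1 met that choice at 1.66%, so its mixed change is no separate support. T3 over that mixture gave log2 changes of -1.79 for FN1 and -1.35 for CXCL8, against -2.11 and -1.46 observed on that scale. In the fit with GC and length correction 4 matrix genes fell and 1 rose. The matrix and cytokine lists then passed camera at the preset correlation (camera adjusted p = 0.0204 and 0.0101). Without T3 replicate 1 or T3 replicate 2 of 6 h 3 matrix genes fell, and 4 without vehicle replicate 2, while cytokine genes falling numbered 2 without vehicle replicate 1 or T3 replicate 1, 3 without vehicle replicate 2 and 1 without T3 replicate 2. The rising matrix and cytokine genes lost their calls without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h, and 1 matrix gene rose without vehicle replicate 2.

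Of 18 genes of the epithelial-mesenchymal state 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.368 with an estimated correlation), and 3 of the 4 were at least 8-fold higher at 24 h. Of 25 cholesterol synthesis genes 5 rose (5 adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.368 with an estimated correlation), led by HMGCS1, from 124 ± 7.24 to 246 ± 15.7 CPM. Of 32 cell cycle genes 3 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.411 with an estimated correlation). These lists missed the threshold in most leave-outs. The epithelial-mesenchymal list held only without T3 replicate 1 of 6 h or either 24 h vehicle library (highest camera adjusted p = 0.128). The cholesterol list held only without vehicle replicate 1 or T3 replicate 2 of 6 h (highest camera adjusted p = 0.267), and the cell cycle list only without either 24 h vehicle library (highest camera adjusted p = 0.0837, and 0.0878 with GC and length correction). All 5 called cell cycle genes lost their calls without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h. Cholesterol genes that rose numbered 1 without vehicle replicate 1 or T3 replicate 1 and 2 without vehicle replicate 2 or T3 replicate 2 of 6 h, and 1 gene of the epithelial-mesenchymal list fell without T3 replicate 2. After GC and length correction 3 cholesterol genes and 1 cell cycle gene rose. The cholesterol and epithelial-mesenchymal lists then passed camera at the preset correlation (camera adjusted p = 0.0101 and 0.0395). Of 6 thyroid differentiation genes PAX8 and THRA fell (2 adjusted over the list alone; camera adjusted p = 0.0216, adjusted p = 0.368 with an estimated correlation). Without vehicle replicate 2 or T3 replicate 2 at 6 h the list missed the threshold (highest camera adjusted p = 0.0702). PAX8, a thyroid transcription factor gene, stood at 11.7 ± 2.51 and 4.18 ± 0.226 CPM (edgeR adjusted p = 0.012, and 0.0543 with GC and length correction), against 134 ± 28.9 CPM in the libraries labelled vehicle at 24 h. T3 over the same mixture with the 24 h profile, taken to stand for vehicle, would give PAX8 a log2 change of -1.01, against -1.38 observed. PAX8 and THRA each lost their call without any 1 of the 6 h libraries (highest edgeR adjusted p = 0.15 and 0.457).

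The other lists tested with camera did not pass at 6 h without correction. Of 24 classical receptor targets KLF9 and HR rose (2 adjusted over the list alone; camera adjusted p = 0.195). Of 19 receptors, partners and transporters 3 fell (4 adjusted over the list alone; camera adjusted p = 0.195), and of 26 SWI/SNF subunits SS18 alone rose (edgeR adjusted p = 0.0486; camera adjusted p = 0.249). The SWI/SNF list passed as higher with GC and length correction (camera adjusted p = 0.0187). SS18 lost its call with that correction (edgeR adjusted p = 0.184), with a replicate block within time, in DESeq2 (DESeq2 adjusted p = 0.0653) and without any 1 of the 6 h libraries (highest edgeR adjusted p = 0.366). Adjusted over the list alone, 0 SWI/SNF subunits passed in edgeR, where 5 were higher and 2 lower at an unadjusted p under 0.05. DESeq2 called SMARCC1 alone (DESeq2 adjusted p = 0.0429), a gene named here after its values were seen. THRB, the TR-beta gene, had a log2 fold change of -0.66 (SE 0.36, edgeR adjusted p = 0.3) and SMARCA4, the ATPase gene BRG1, of -0.10 (SE 0.11, edgeR adjusted p = 0.64). Among interferon and JAK-STAT genes 4 of 32 fell (4 adjusted over the list alone; camera adjusted p = 0.195), and among histones 2 of 31 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.195). Every falling interferon gene and every falling gene of the receptor and transporter list lost its call without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h. Without vehicle replicate 2 of 6 h 2 interferon genes and 1 gene of the receptor and transporter list were called lower, and in the latter list 5 without either 24 h vehicle library. Each list had 2 lower with GC and length correction. Histones called lower numbered 1 without any 1 of the 6 h libraries, where the rising one lost its call, and 6 without either 24 h vehicle library. Immediate early genes (1 of 22 up, 1 down; 1 and 2 adjusted over the list alone; camera adjusted p = 0.135) and glycolysis and hypoxia genes (1 of 30 up, 2 down; 3 and 3 adjusted over the list alone; camera adjusted p = 0.484) moved in few members. So did fatty acid genes (1 of 26 up; 1 adjusted over the list alone; camera adjusted p = 0.219) and Wnt and Notch targets (1 of 13 up; 1 adjusted over the list alone; camera adjusted p = 0.628). The called immediate early, fatty acid, and Wnt and Notch genes and the rising glycolysis gene lost their calls without any 1 of the 6 h libraries. Glycolysis genes called lower numbered 1 without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h, and those called higher 2 without any 1 of the 24 h libraries, while 2 immediate early genes were then called lower. None of the 13 mitochondrially encoded genes passed in edgeR, at an unadjusted p under 0.05 or in DESeq2 (camera adjusted p = 0.0534, passing only without vehicle replicate 2 of 6 h or either 24 h vehicle library, lowest 0.00914). Without either 24 h vehicle library 1 of them was called higher.

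The GC content of genes went with the changes at both times. With annotated genes in 5 bins by GC content, median log2 fold changes went from 0.29 in the lowest bin to -0.32 in the highest at 6 h, and from 0.33 to -0.52 at 24 h in the libraries labelled T3 over those labelled vehicle. With that trend and the one with length removed, 155 genes were higher and 294 lower at 6 h. Of 1118 calls among annotated genes at 6 h, 376 were kept in the same direction, 117 higher and 259 lower. Without a filter on low counts 917 were higher and 537 lower. The 6 h count also rested on single libraries: it was 130 without vehicle replicate 1, 564 without vehicle replicate 2, 132 without T3 replicate 1 and 137 without T3 replicate 2 of that time.

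**Figure D2:**
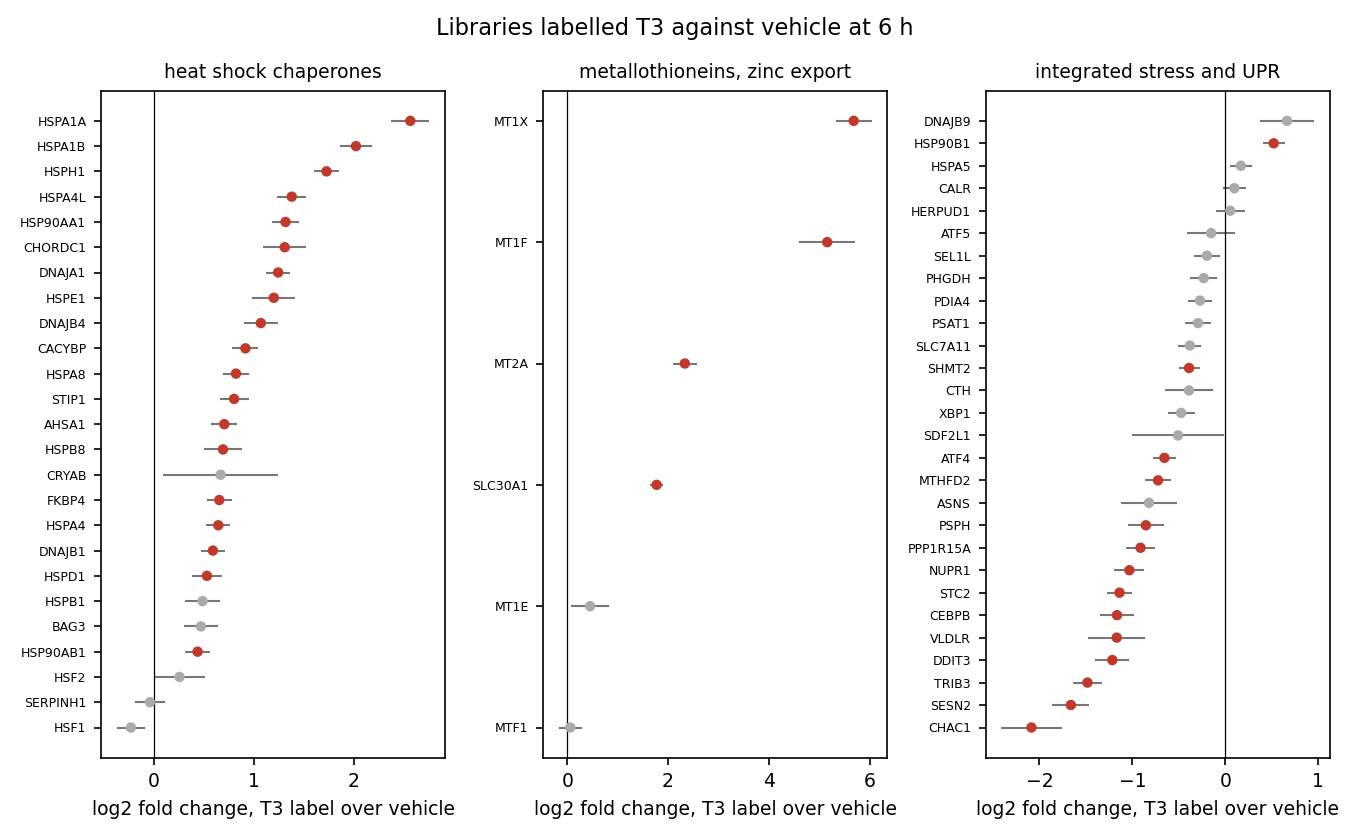
Log2 fold change of T3 over vehicle at 6 h (points, with SE bars) for tested heat shock chaperones, metallothioneins with zinc export, and integrated stress and unfolded protein response genes. Red points passed an edgeR adjusted p of 0.05 and grey ones did not. This leaves 19 of 25 chaperones and 4 of 6 genes of metallothioneins and zinc export higher, and 13 of 28 stress response genes lower.

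**Figure D3:**
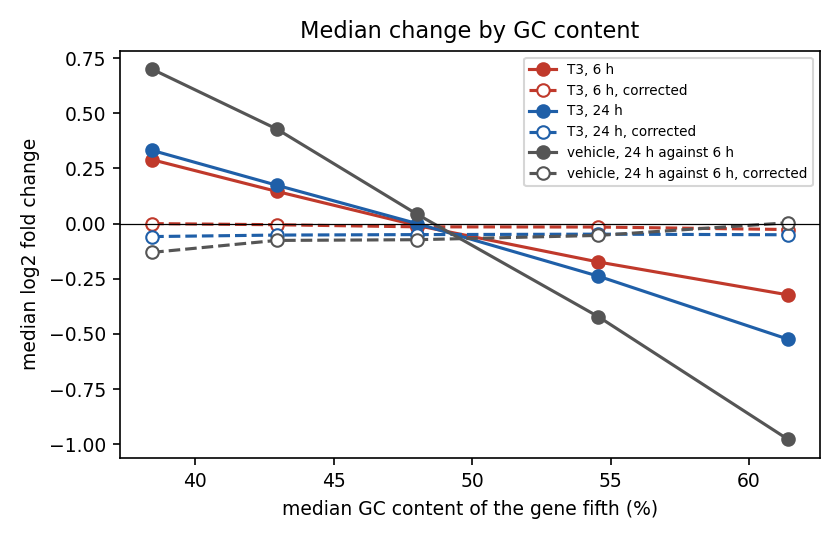
Median log2 fold change (vertical axis) in 5 bins of annotated genes against their median GC content in percent (horizontal axis) for the 3 comparisons of groups, before correction (solid lines) and after (dashed lines). Before correction the medians fall from 0.29 to -0.32 for T3 at 6 h, 0.33 to -0.52 for the libraries labelled T3 at 24 h, and 0.70 to -0.98 for 24 h against 6 h.

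At 24 h, 8 of 23 p53 target genes were higher and 16 of 31 replication-dependent histone genes lower in the libraries labelled T3, labels that KLF9 and HR go against. The lists had camera adjusted p = 0.00172 and 2.17e-07, and adjusted p = 0.274 and 0.386 with an estimated correlation. MDM2, the p53 ubiquitin ligase gene, stood at 394 ± 12.4 CPM in the libraries labelled vehicle and 805 ± 23.3 CPM in those labelled T3 (SD, n = 2 per group; log2 fold change 1.03, SE 0.12, edgeR adjusted p = 0.00025). HIST1H2AG stood at 97.3 ± 3.02 and 53.6 ± 3.34 CPM (log2 fold change -0.86, SE 0.12, edgeR adjusted p = 0.000657). COL9A2, a collagen gene, went from 14.3 ± 1.99 to 0.811 ± 0.489 CPM, and HSPG2, which encodes perlecan, from 679 ± 5.35 to 300 ± 5.01 CPM (edgeR adjusted p = 0.00012 and 6.75e-05).

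Of the 14611 genes, 1948 passed at 24 h, 816 higher and 1132 lower in the libraries labelled T3, 399 of them changed at least 2-fold (edgeR with Benjamini-Hochberg adjustment). Calls of at least 2-fold numbered 859 without T3 replicate 1 and 568 without T3 replicate 2 of 24 h, 191 with only the 4 libraries compared and 57 with GC and length correction. PITX1, a homeobox gene, had 1 count in the libraries labelled T3, a ratio of 40.7 with a counting interval of 6.77 to 1662. SCNN1A, a sodium channel subunit gene, had none there and was at least 13.1-fold lower. CORO7, a coronin gene, was lower by a log2 fold change of -4.27 (SE 0.66), HEG1 of -1.13 (SE 0.11), the ribosomal protein gene RPL28 of -1.39 (SE 0.15), the stress-induced gene NUPR1 of -1.51 (SE 0.18) and the interferon-induced gene IFITM3 of -1.27 (SE 0.17). LRP1B was higher by 2.66 (SE 0.49) and AMN1 by 1.74 (SE 0.28). SPATA31D1 had 3 counts in the libraries labelled vehicle, a ratio of 30.2 with a counting interval of 10.1 to 148, and its libraries labelled T3 differed widely at 7.45 ± 6.81 CPM. Of the 77 named genes past the threshold, 35 kept their call in every leave-out and 17 of those also with GC and length correction.

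Of 23 p53 targets 8 were higher (10 adjusted over the list alone; camera adjusted p = 0.00172, adjusted p = 0.274 with an estimated correlation), among them CDKN1A, the p21 gene, from 65.7 ± 0.358 to 109 ± 20.8 CPM. CDKN1A lost its call without T3 replicate 2 of 24 h (edgeR adjusted p = 0.0502), with log2 fold changes of 0.53 to 0.92 over the leave-outs. With GC and length correction 5 were higher, while the list median went from 0.30 to 0.43 on the log2 scale. The list still passed camera at the preset correlation (camera adjusted p = 3.00e-09). Of 31 histone genes 16 were lower (19 adjusted over the list alone; camera adjusted p = 2.17e-07, adjusted p = 0.386 with an estimated correlation). With GC and length correction 5 were lower (camera adjusted p = 0.00102 at the preset correlation). Without T3 replicate 2 of 24 h 9 histone genes were lower, and 5 p53 targets higher. Without vehicle replicate 1 of 24 h 12 histone genes were lower and 2 higher. HIST1H1E had a log2 fold change of -1.08 (SE 0.13, edgeR adjusted p = 0.000205, and 0.0646 with the correction) and HIST2H2BF of -0.83 (SE 0.15). Beside these lists, 24 h vehicle replicate 2 stood apart in mitochondrial RNA. Mitochondrially encoded messengers took 7.95% of its gene counts, against 3.13% in vehicle replicate 1 and 4.28% and 4.03% in the libraries labelled T3. None of the 13 genes passed in edgeR, at an unadjusted p under 0.05 or in DESeq2. Without vehicle replicate 1 of 24 h 7 of them were called lower. As a list they passed camera only without vehicle replicate 1 or vehicle replicate 2 of 24 h. The first sets the libraries labelled T3 against a vehicle share of 7.95%, above theirs, and the other against 3.13%, below theirs. The 2 leave-outs therefore show no common direction.

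Other lists did not pass at 24 h. Of 24 classical receptor targets 5 were lower and 1 higher in the libraries labelled T3 (6 and 1 adjusted over the list alone; camera adjusted p = 0.355). KLF9 and HR alone of them kept their calls with GC and length correction. The higher 1, TXNIP, named here after its values were seen, had an edgeR adjusted p = 0.036, and 0.307 with the correction, and lost its call without any 1 of the libraries other than vehicle replicate 1 of 6 h. Of 26 SWI/SNF subunits 3 were lower and 2 higher (9 and 2 adjusted over the list alone; camera adjusted p = 0.355, and 0.0226 without vehicle replicate 1 of 24 h). The 2 higher subunits, PHF10 and ACTL6A, lost their calls without T3 replicate 1 or T3 replicate 2 of 6 h or replicate 2 of vehicle or T3 at 24 h, and PHF10 also without T3 replicate 1 of 24 h (highest edgeR adjusted p = 0.0744 and 0.157). All 5 called subunits lost their calls with GC and length correction. SMARCA4 stood at 188 ± 14.2 and 130 ± 0.803 CPM, a log2 fold change of -0.54 (SE 0.11, edgeR adjusted p = 0.0071) that went to -0.09 with GC and length correction (edgeR adjusted p = 0.704). THRB had a log2 fold change of -0.03 (SE 0.21, edgeR adjusted p = 0.946), and THRA of -0.70 (SE 0.19, edgeR adjusted p = 0.0238, and 0.408 with the correction). THRA lost its call without either T3 replicate at 6 h, vehicle replicate 2 or T3 replicate 2 at 24 h (highest edgeR adjusted p = 0.156). Of 28 stress response genes 7 were lower and 4 higher (8 and 4 adjusted over the list alone; camera adjusted p = 0.689). NUPR1 alone of the 11 kept its call with GC and length correction. Lower and higher ones numbered 2 and 2 without T3 replicate 1 or T3 replicate 2 of 6 h, 4 and 4 without vehicle replicate 1, 6 and 1 without vehicle replicate 2, 3 and 2 without T3 replicate 1 and 4 and 2 without T3 replicate 2 of 24 h. Of 22 matrix genes 5 were lower and 2 higher (6 and 3 adjusted over the list alone; camera adjusted p = 0.664). The 5 lower ones lost their calls with the correction. Without T3 replicate 2 of 24 h 3 were lower and both higher ones lost their calls, and 4 were lower and 1 higher without T3 replicate 1 or T3 replicate 2 of 6 h or vehicle replicate 2 of 24 h.

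With GC and length correction 60 genes were higher and 189 lower in the libraries labelled T3, and 184 of 1993 calls among annotated genes were kept in the same direction. Without T3 replicate 1 or T3 replicate 2 at 6 h, which add only to the shared estimate of spread, 1133 and 1147 genes passed.

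**Figure D4:**
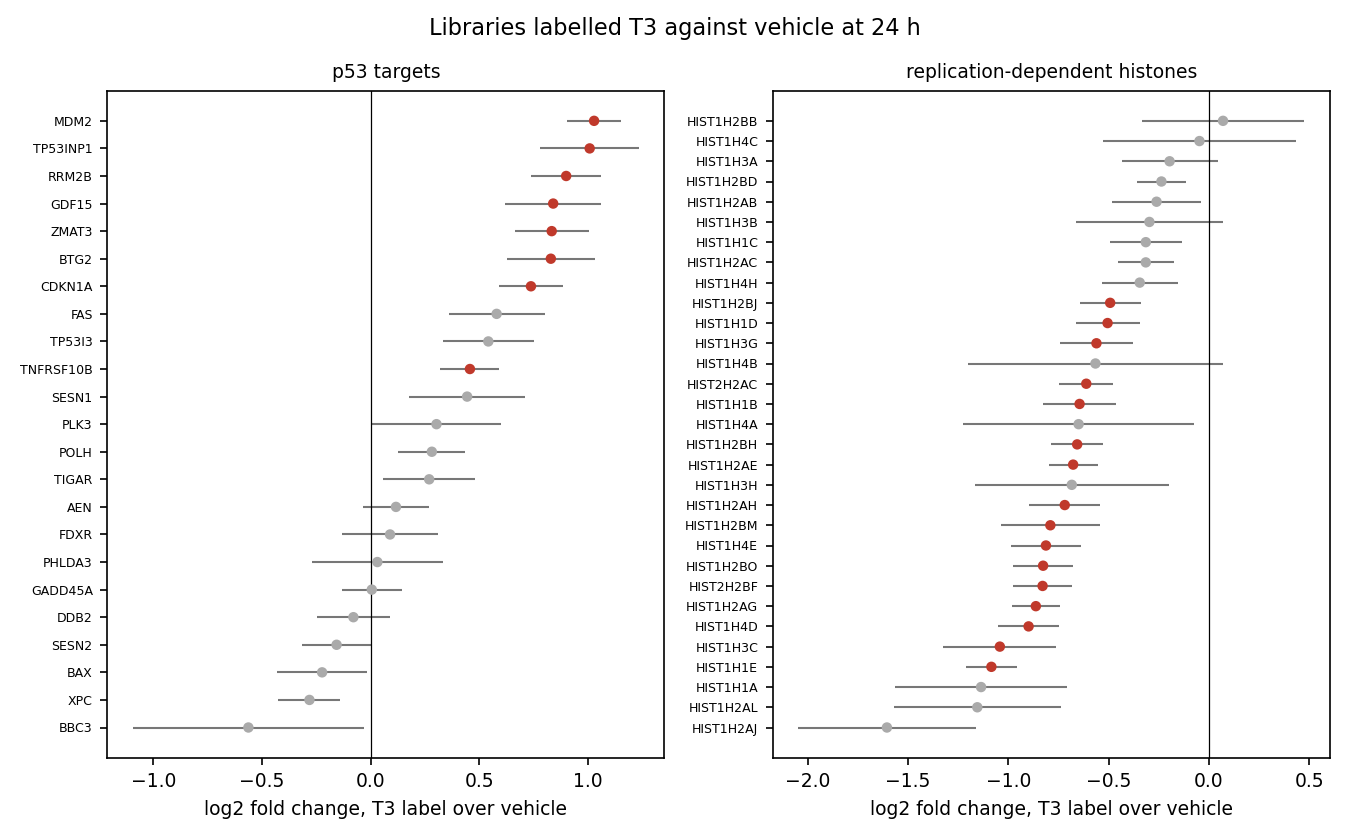
Log2 fold change at 24 h of the libraries labelled T3 over those labelled vehicle (points, with SE bars) for p53 targets and replication-dependent histone genes, under labels that KLF9 and HR go against. Red points passed an edgeR adjusted p of 0.05 and grey ones did not: 8 of 23 p53 targets are higher and 16 of 31 histone genes lower, or 5 and 5 with GC and length correction. Both lists passed camera with that correction too, at the preset correlation (camera adjusted p = 3.00e-09 and 0.00102).

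The T3 responses at both times were compared by an interaction term. Libraries labelled vehicle themselves differed between the times in 64.5% of the genes tested. A change of response over time therefore cannot be told apart from different cells at the 2 times. The log2 fold change in the 24 h libraries as labelled, less that at 6 h, was -7.03 for KLF9 (SE 0.57, edgeR adjusted p = 4.08e-06), -6.34 for MT1X (SE 0.85, edgeR adjusted p = 0.000849) and -4.96 for HR (SE 0.54, edgeR adjusted p = 0.000128). KLF9, MT1X and HR alone of the 11 genes named for this comparison kept their call in every leave-out. MT1X, 51.4-fold higher with T3 at 6 h, stood at 1.20 ± 0.418 CPM in the libraries labelled vehicle and 0.714 ± 0.790 CPM in those labelled T3 at 24 h. HEG1, named for its fall at 24 h, rose at 6 h by 1.45 on the log2 scale (SE 0.12) and differed by -2.58 (SE 0.17, edgeR adjusted p = 2.92e-07). In the other direction MEIOC differed by 3.86 (SE 0.56), a call lost without T3 replicate 2 of 6 h (edgeR adjusted p = 0.0667).

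In all 269 genes differed in response, 124 with a higher and 145 with a lower log2 fold change in the 24 h libraries as labelled (edgeR with Benjamini-Hochberg adjustment). Without a filter on low counts the split was 199 and 475. The count was 116 without vehicle replicate 1, 53 without vehicle replicate 2, 67 without T3 replicate 1 and 45 without T3 replicate 2 at 6 h, and 654 without vehicle replicate 1 at 24 h. Across genes, which are not independent replicates, log2 fold changes at the times correlated with a Pearson r of 0.166 and a Spearman rho of 0.313. Of 310 genes called at both times 282 went the same way, 164 higher and 118 lower, where independent lists would share 30.9 and 43.7. Genes called at both times numbered 36 without vehicle replicate 1, 150 without vehicle replicate 2, 32 without T3 replicate 1 and 37 without T3 replicate 2 of 6 h, and 195 without T3 replicate 2 of 24 h. With GC and length correction 29 were called at both, 16 of them the same way, and r was 0.00043.

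Cultures labelled vehicle differed between the times more than T3 and vehicle did at either time. Genes abundant at 6 h were absent from the 24 h counts: TM4SF1, which encodes a tetraspanin-like membrane protein, stood at 874 ± 1.5 CPM at 6 h (SD, n = 2) and had no count at 24 h, at least 3240-fold lower. ALPI, an alkaline phosphatase gene, at 539 ± 63.8 CPM, and GDA, the guanine deaminase gene, at 412 ± 38.9 CPM, also had none, at least 2022-fold and 1509-fold lower. KRT17, a keratin gene, went from 543 ± 79.7 CPM to 1 count. FN1 stood at 551 ± 134 CPM at 6 h and 8434 ± 808 CPM at 24 h.

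Of the 14611 genes 9424 passed between the times in the libraries labelled vehicle, 4668 higher and 4756 lower at 24 h, which is 64.5% of those tested, and 6315 changed at least 2-fold (edgeR with Benjamini-Hochberg adjustment). Over T3 and vehicle together, 25 genes had at least 50 CPM in every 6 h library and at most 3 counts over all 24 h libraries. The reverse held for 0 genes, though 825 genes were at least 8-fold higher in the 24 h libraries and 880 in the 6 h ones. Among the largest falls, CPS1, the urea cycle carbamoyl phosphate synthetase gene, went from 2858 ± 16.9 to 11.3 ± 2.87 CPM, ALPP, the placental alkaline phosphatase gene, from 1045 ± 143 to 0.636 ± 0.580 CPM, and MYC from 1327 ± 35.7 to 41.5 ± 4.07 CPM. Among the rises from no count, ZNF471 and ZNF525, zinc finger genes, and MAL were at least 38.4-fold, 34.6-fold and 23.0-fold higher.

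Cholesterol and sugar metabolism genes were lower at 24 h in the libraries labelled vehicle. Of 25 cholesterol synthesis genes 18 fell (19 adjusted over the list alone; camera adjusted p = 0.000157, adjusted p = 0.189 with an estimated correlation). Among them SREBF2, a regulator of the pathway, fell by 2.05 on the log2 scale (SE 0.15). Of 30 glycolysis and hypoxia genes 20 fell and 5 rose (21 and 5 adjusted over the list alone; camera adjusted p = 0.00832, adjusted p = 0.349 with an estimated correlation), with GPI by 3.51 (SE 0.13) and GAPDH from 5220 ± 197 to 1471 ± 106 CPM. Of 24 classical receptor targets 17 fell and 6 rose (17 and 6 adjusted over the list alone; camera adjusted p = 0.0323, adjusted p = 0.229 with an estimated correlation), with FASN and SREBF1, both of lipid synthesis, lower and KLF9 higher. The list of receptor targets missed the threshold with GC and length correction (camera adjusted p = 0.0703). Of 26 fatty acid genes 12 fell and 5 rose (12 and 5 adjusted over the list alone; camera adjusted p = 0.115, and 0.0181 with GC and length correction), with SCD from 769 ± 10.1 to 80.6 ± 3.49 CPM.

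Matrix and cytokine genes were higher at 24 h. Of 22 matrix and TGF-beta genes 16 rose and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.189 with an estimated correlation), with SPARC by 3.46 (SE 0.16) and COL1A1 by 2.64 (SE 0.13) on the log2 scale. Of 18 NF-kB and cytokine genes 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.00866, adjusted p = 0.189 with an estimated correlation), with CXCL8 from 20.2 ± 4.34 to 248 ± 3.69 CPM and ICAM1 from 6.78 ± 1.49 to 115 ± 15.3 CPM. Of 31 histone genes 21 fell and 5 rose (22 and 5 adjusted over the list alone; camera adjusted p = 0.00393, adjusted p = 0.352 with an estimated correlation). With GC and length correction the histones split into 12 lower and 12 higher, and the camera direction turned (adjusted p = 0.804).

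Few thyroid genes were counted at any time. PAX8 was 11.7-fold and THRB 4.59-fold higher at 24 h, and THRA 2.53-fold lower (edgeR adjusted p = 2.67e-10, 2.70e-06 and 7.01e-06). Of 6 thyroid differentiation genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.356). Thyroglobulin (TG) had 7 counts over all 8 libraries, TSHR 3, the iodide transporter gene SLC5A5 16, NKX2-1 6, DUOX1 37, and the deiodinase genes DIO1 2 and DIO2 27, too few to test. FOXE1 had a log2 fold change of 0.73 at 24 h against 6 h (SE 0.31, edgeR adjusted p = 0.0479) and lost its call without any 1 of the 4 vehicle libraries (highest edgeR adjusted p = 0.183). Among markers of other cell types, no endothelial gene was abundant enough to test. The fibroblast genes FAP and DCN fell to no count (at least 13.5-fold and 11.6-fold lower) while COL1A1 rose. The immune marker CSF1R fell by 7.03 on the log2 scale (SE 0.36). Thus 1 of 4 tested fibroblast genes was higher and 2 lower (1 and 2 adjusted over the list alone). Of 2 tested C cell genes CHGB rose, from 2 counts, a ratio of 13.0 with a counting interval of 3.40 to 110, and lost its call without vehicle replicate 1 of 6 h or vehicle replicate 2 of 24 h (highest edgeR adjusted p = 0.156).

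The remaining lists did not pass between the times without correction. Cell cycle genes split into 13 higher and 12 lower of 32 (13 and 13 adjusted over the list alone; camera adjusted p = 0.641). SWI/SNF subunits split into 12 and 8 of 26 (12 and 8 adjusted over the list alone; camera adjusted p = 0.646), and interferon and JAK-STAT genes into 19 and 8 of 32 (19 and 8 adjusted over the list alone; camera adjusted p = 0.06). The interferon list passed without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h or vehicle replicate 2 of 24 h (lowest camera adjusted p = 0.0383), and with GC and length correction (camera adjusted p = 0.0132). Mitochondrially encoded genes had camera adjusted p = 0.115, and 0.0181 with the correction. In edgeR 0 of the 13 passed, 1 was higher at an unadjusted p under 0.05, DESeq2 called 3 higher, and 11 were called higher without vehicle replicate 1 of 24 h. SMARCA4 fell by 0.82 on the log2 scale (SE 0.11, edgeR adjusted p = 8.55e-06) and SMARCC1 by 0.94 (SE 0.11, edgeR adjusted p = 1.28e-06). Ribosomal protein genes took 5.96% to 6.54% of counts in the 6 h libraries and 2.23% to 3.03% in the 24 h ones, and the nuclear transcript MALAT1 0.358% to 0.486% and 1.95% to 2.42%. The first principal component, which parted the times, held 83.9% of the variance. Pearson correlations of log2 CPM across genes were at least 0.958 between libraries of 1 time and between 0.687 and 0.769 across times. The sample labels state no collection day or sequencing run, so any that went with time cannot be told apart from it. With GC and length correction 7736 genes passed, and leaving out single libraries gave 7338 to 10001.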

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

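The test of exchanged labels after GC and length correction and the test for reads of the 6 h cells were chosen only after the result was seen. The T3 response differed between the times in 269 genes by an edgeR interaction term, with directions taken from the 24 h libraries as labelled. The log2 fold change at 24 h less that at 6 h was -7.03 for KLF9, -6.34 for MT1X and -4.96 for HR, and these calls held in every leave-out. It was -6.89 for TNS4, lost without vehicle replicate 2, T3 replicate 1 or T3 replicate 2 of 6 h or vehicle replicate 2 of 24 h (highest edgeR adjusted p = 0.156). It was -5.51 for COL4A3, which among the leave-outs held only without vehicle replicate 1 of 24 h (highest edgeR adjusted p = 0.142), and -5.36 for ELMO3, which held only without vehicle replicate 2 of 24 h (highest edgeR adjusted p = 0.154). On the other side it was 3.47 for CNRIP1 and 3.56 for DPY19L2P2, both lost without vehicle replicate 2 or T3 replicate 2 of 6 h (highest edgeR adjusted p = 0.176 and 0.0833), and 3.86 for MEIOC, lost without T3 replicate 2 of 6 h (edgeR adjusted p = 0.0667). It was 3.46 for GNG7, lost without any 6 h library or vehicle replicate 2 of 24 h (highest edgeR adjusted p = 0.256), and 4.05 for PIEZO2, which held only without vehicle replicate 1 or T3 replicate 1 of 24 h (highest edgeR adjusted p = 0.216).

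KLF9 and HR were higher with T3 at 6 h and lower in the libraries labelled T3 at 24 h. GC content and gene length were argued against as the whole cause, since HR kept 87.1% and KLF9 104% of the 24 h log2 fold change with the correction, and so were reads of the 6 h cells in the libraries labelled vehicle at 24 h, where 30 genes of the 6 h libraries had a median of 0% of their 6 h level. Exchanged vehicle and T3 labels at 24 h may account for the pattern and stay open: of 308 genes called at both times apart from KLF9 and HR, 26 went opposite ways, or 8.44% (exact 95% interval 5.59% to 12.1%), which met the bound set beforehand against an exchange. That bound does not settle it, because changes went with GC content the same way at both times under the labels as written. If that shared trend is technical, it says nothing about the labels. With correction 11 of 27 went opposite ways, or 40.7% (22.4% to 61.2%). A response to T3 that turns by 24 h was not tested apart from an exchange, and the 24 h labels and the direction of these genes cannot be told apart with 2 libraries per group. Different cells at the 2 times, which also stay open, were not tested apart from either. The share of opposite signs can speak to the labels only if the cells of both times respond to T3 alike.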

How the results depend on the processing

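The GC and length correction, thinning, annotated genes alone, and leaving out mitochondrial genes or genes over 8-fold higher at 24 h were chosen only after the data were seen. With RLE size factors, the 1 CPM filter, DESeq2, thinning and no mitochondrial genes, the 4 counts of genes stayed within 1.5 times their values. T3 at 6 h gave 1117 genes, 3111 with only the 4 libraries compared, 449 with GC and length correction, 234 with correction and the replicate block, and 130 to 1631 without single libraries (130 without vehicle replicate 1, 564 without vehicle replicate 2, 132 without T3 replicate 1 and 137 without T3 replicate 2 of 6 h). T3 at 24 h by label gave 1948, 800 with its 4 libraries, 249 with correction, 58 with correction and block, and 1133 to 2034 without single libraries (1133 without T3 replicate 1 and 1147 without T3 replicate 2 of 6 h). The interaction gave 269, 674 without a filter (with a median of -0.12 on the log2 scale, against -0.0116), 153 with correction and block, and 45 to 654 without single libraries (116, 53, 67 and 45 without vehicle replicates 1 and 2 and T3 replicates 1 and 2 of 6 h, and 654 without vehicle replicate 1 of 24 h). Fits to 4 libraries estimate the spread from fewer samples, yet with them calls rose at 6 h and fell at 24 h. The main fit shares 1 spread over both times, but the replicates did not spread equally. Chi-square per degree of freedom, which also grows with depth, was 4.11 and 2.69 at 6 h, and 27.8 and 7.24 at 24 h. Adjusted p-values of the main fit may thus be too small at 24 h and too large at 6 h. Beyond that the cause was not tested.

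Of 19 lists tested with camera, 7 passed for T3 at 6 h, 2 at 24 h and 6 between the times. With an estimated correlation 0, 0 and 0 passed, while 3, 2 and 3 had an unadjusted p under 0.05. Without single libraries 4 to 7, 2 to 4 and 6 to 7 passed. At 24 h by label the median log2 fold change and the camera direction differed in sign for the cell cycle, Wnt and Notch, and metallothionein lists. The Pearson r across genes between the T3 responses, 0.166, was 0.00043 with correction and 0.103 to 0.197 without single libraries. Same-numbered libraries did not deviate together (correlations of -0.0036 at 6 h and -0.0437 at 24 h), so the numbers were not taken as pairs. A replicate block within times gave 883, 1641 and 246 genes for T3 at 6 h, T3 at 24 h and the interaction, and a block by number across the times 1232, 2057 and 321, with 9350 between the times.

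Directions were followed only in named genes past the threshold and in KLF9, HR, THRA, THRB, SMARCA4, PAX8 and FOXE1. Among these they turned in 6 genes, with those at 24 h by label, and the cause was not tested. Other genes were not checked for a turn. With correction, and with correction and block, the log2 fold change was 0.24 and 0.24 for SMARCA4 at 6 h, and at 24 h -0.0609 and -0.0603 for CXCL8, 0.0711 and 0.0697 for NFKB2, 0.0265 and 0.0435 for PAX8, and 0.35 and 0.33 for FOXE1. FOXE1 at 24 h was 0.0651 after thinning and -0.39 to 0.18 without single libraries (0.18 without T3 replicate 2), and at 6 h -0.96 to 0.0835 (0.0835 without T3 replicate 2). THRB at 24 h was -0.24 to 0.24, turning without vehicle replicate 2 (0.24) or T3 replicate 2 (0.09). Of these, CXCL8 and NFKB2 at 24 h had passed the edgeR threshold. Depth limits genes near 1 CPM most, where 3 counts stood for 0.366 to 1.19 CPM.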

Other observations

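The heat shock, metallothionein and ribosomal protein lists, the tests of 24 h reads in the 6 h vehicle libraries and the test of T3 acting alone were chosen only after the results were seen. Camera p-values of the 3 lists were adjusted over the 3 alone, and lists picked from the same data give no separate support. With an estimated correlation the unadjusted camera p at 6 h was 0.0105 for heat shock, close to 0.00991 for the stress response list. Heat shock chaperone genes, whose proteins fold others, rose with T3 at 6 h: 19 of 25 (21 adjusted over the list alone; camera adjusted p = 1.15e-14, adjusted p = 0.0316 with an estimated correlation). HSP90AA1 rose by 1.32 (SE 0.13), DNAJA1 by 1.25 (SE 0.12) and HSPA4L by 1.38 (SE 0.14) on the log2 scale. Without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h, 9, 10 and 11 chaperone genes rose. In the libraries labelled T3 at 24 h 2 were higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.795), HSPE1 being higher by 1.62 (SE 0.23). Higher and lower ones numbered 2 and 4 without vehicle replicate 1 of 24 h, 1 and 1 without replicate 2 of vehicle or T3 at 24 h, and 1 and 2 without either T3 library of 6 h. After GC and length correction 1 was higher and both lower ones lost their calls. Of 6 tested genes of metallothioneins and zinc export 4 rose at 6 h in every leave-out (4 adjusted over the list alone; camera adjusted p = 9.98e-07, adjusted p = 0.0788 with an estimated correlation). At 24 h by label 1 of the 6 was higher and 1 lower (1 and 2 adjusted over the list alone; median log2 fold change -0.22, camera adjusted p = 0.98). SLC30A1 was the higher, by 0.90 (SE 0.12, edgeR adjusted p = 0.000474), and MT2A the lower, by 1.20 (SE 0.25, edgeR adjusted p = 0.0111, and 0.257 with GC and length correction), a call lost without T3 replicate 1 or T3 replicate 2 of 24 h. Without vehicle replicate 1 of 24 h 2 were lower.

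Cytosolic ribosomal protein genes were lower in the libraries labelled T3 at 24 h, 22 of 76, with 1 higher (25 and 1 adjusted over the list alone; camera adjusted p = 0.00118, adjusted p = 0.815 with an estimated correlation). With GC and length correction 16 were lower and 1 higher. With T3 at 6 h 2 of the 76 rose and 1 fell (1 and 1 adjusted over the list alone), with the list higher (camera adjusted p = 0.00107, adjusted p = 0.305 with an estimated correlation). The called ones lost their calls without vehicle replicate 1, T3 replicate 1 or T3 replicate 2 of 6 h, and 11 rose without either 24 h vehicle library. At 24 h by label 12 were lower without T3 replicate 2 of 24 h, and without vehicle replicate 1 of 24 h 21 were lower and 12 higher. Between the vehicle libraries 68 of 76 fell and 1 rose at 24 h (68 and 1 adjusted over the list alone; camera adjusted p = 9.46e-13, adjusted p = 0.176 with an estimated correlation).

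The 6 h and 24 h libraries labelled vehicle differed in 9424 genes. GC content and length were argued against as the whole cause, since 7736 genes passed with the correction against 8508 among annotated genes without it, of which 5953 (70.0%) were kept in the same direction, and depth likewise, with 9136 passing after thinning. Different cells at the 2 times may account for it and stay open: medians of 232 runs of 50 neighbouring genes had an SD 2.15 times that of shuffled genes, between the bounds of 1.5 and 3 set beforehand. The same ratio was 1.36 for T3 at 6 h and 1.29 for T3 at 24 h by label. Between the times the SD was 0.378, against 0.206 for the highest of 200 shuffles. In both T3 comparisons it also exceeded every shuffle. Among the genes of the 6 h libraries only, HOXA13 and HOXA10, chosen afterwards, had 1121 and 998 counts at 6 h and 0 at 24 h. A change of the same cells in culture was not tested apart from different cells, since time, collection and any difference of cells cannot be told apart here.

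Genes high at 24 h were lower with T3 than with vehicle at 6 h, and reads or cells of the 24 h kind in the 6 h vehicle libraries may account for part of it. Of genes with at least 50 CPM in all 24 h libraries, 0 had at most 3 counts over the 6 h libraries, against 25 in reverse. Reads of the 24 h kind in every 6 h library, T3 included, were not tested as its cause. Over 20 genes, chosen through T3 replicate 1, which favours the pattern, the vehicle libraries held a median of 4.51% and 6.21% of the 24 h level, the lower 3.21 times that of T3 replicate 2, yet upper quartiles were up to 3.2 times lower ones, where 1 source needs a single ratio, so this stays open. With 63 genes chosen by their mean the medians were 5.93% and 8.36% with vehicle and 2.63% and 2.5% with T3, and upper quartiles were 1.87 and 1.7 times lower ones with vehicle. For mixing, the test asked for quartile ratios under 2 and medians over 1.5 times that of T3 replicate 2. The 63 genes lay within both bounds, while the 20 genes missed the first. A response to T3 alone met its test: with a further 3.99% of the 24 h profile mixed in, 59.4% of the median fall was left over the 164 genes that fell at least 2-fold and were at least 8-fold higher at 24 h than with T3 at 6 h. Over all 328 genes that fell at least 2-fold it was 72.6%, a value raised by the other 164, where 94.5% was left. All were picked for large falls, which favours that outcome, and mixing is not excluded. The share of 3.99% was itself the mean vehicle median less the mean T3 median over the 20 genes, FN1 among them. Mixed changes were -1.79 of -2.11 observed for FN1, -1.35 of -1.46 for CXCL8, -1.01 of -1.38 for PAX8 and -1.57 of -2.01 for ICAM1, so for these most of the fall could also come from mixing, while the vehicle libraries held 5.72% and 8.09% of the 24 h level of FN1 but 1.67% and 3.81% of that of VCAN.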
